A study of Mus musculus with 3 samples.

How the data were processed

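Bronchoalveolar lavage cells of bleomycin-treated mice, sorted by the authors for CD11b+ or CD11c+ cells, were studied in 3 libraries: WT DMSO, WT GW5074 and KO DMSO (Clec7a knockout), with 1 library per group. Each library came from lavage fluid pooled over the mice of a group, and the number of mice was not given. The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode, for 32286 genes. Per the submitters' processing notes, Cell Ranger 2.1.1 and the mouse genome mm10 were used. The extraction protocol names a SeekOne chip and sequencing of 3' ends with cell barcodes and UMIs, while another label names 10x Genomics. Both describe droplet 3' libraries. Every deposited barcode had at least 500 UMIs, so barcodes had been filtered by the authors before deposit, which removes small cells with little RNA first. Sequencing of 3' ends counts molecules by their tail, so values are not biased by gene length but report nothing on the rest of a transcript.

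Cells with at least 200 genes and at most 20% mitochondrial UMIs were kept, which removed 50, 17 and 36 barcodes and left 42888 cells. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen, scaled with a cap of 10 and reduced to 30 principal components, and cells were clustered by the Leiden method at resolution 1 on a graph of 15 neighbours. All 3 libraries were clustered together without batch correction. The work used Python 3.11.15, scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, pandas 2.3.3 and matplotlib 3.10.9. Doublets were to be removed with Scrublet, but the caller marked 4 cells (0.00933%), under the 0.5% a working caller should mark, so none was removed. Clusters with high doublet scores were left unnamed instead. Of the 25 clusters, 15 were named by markers fixed beforehand and are called X-like. Siglec5, Sepp1 and BC100530 were not among the genes measured.

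The naming thresholds were set after the data had been seen. A marker counted as raised when it was at least 2-fold above the median of clusters, at 20 CPM or more and in at least 10% of the cluster's cells. A name needed at least 3 raised markers and 25% of a class's markers. A cluster stayed unnamed when markers of another class led it, when 2 classes scored alike, when its median doublet score was above 0.1, when cycling or mitochondrial genes led it, or when its median depth was below its library's divided by 3 with no marker among its leading genes. The cell type markers, the gene lists, the rule for named genes, the comparisons and the first set of alternative settings were chosen before the data were examined.

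Shares of kept cells were given with exact Clopper-Pearson intervals. Within the 7 classes of at least 100 cells in each library, UMIs were summed per library and scaled to CPM of the class. Log2 ratios were taken for GW5074 over DMSO in WT, KO over WT under DMSO, and KO over GW5074, with exact conditional binomial intervals of the ratio, and levels with exact Poisson intervals. No p-values, standard errors or counts of changed genes were computed, since cells are not replicates. A count of 0 was replaced by a floor of 3 counts and the fold given as a bound. Gene positions came from GENCODE M21 (GRCm38, mm10, 1-based), which held 32236 (99.8%) of the gene identifiers. That annotation lists Clec7a as a polymorphic pseudogene.

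Named genes needed at least 50 CPM in 1 of the 2 libraries and 100 UMIs over both. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, T cell receptor, predicted and sex-linked genes, Clec7a and all cell type markers were left out. For each comparison against WT DMSO, the 10 highest and 10 lowest log2 ratios were named in the class with the most cells, the resident alveolar macrophage-like class (10056 cells), the 5 highest and lowest in the other macrophage class (10008 cells), and the 2 highest and lowest in each other class. From each list the up to 2 highest and lowest members in the main class were eligible. Which of these the text gives, and the list members named in monocyte-derived macrophage-like cells, were chosen after their values were seen. For 1 gene named by the rule, the result is not reported here.

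The 25 gene lists included 1 of sex-linked genes, used only to check the pools. Its Y-linked genes were alike in all 3 pools, with Ddx3y at 88.2, 82.4 and 74.8 CPM, Eif2s3y at 54.3, 52.3 and 52.0 CPM, Kdm5d at 19.3, 19.2 and 17.9 CPM and Uty at 54.2, 55.0 and 52.6 CPM, while Xist was at 0.18, 0.11 and 0.14 CPM. For the others, the median log2 ratio of members with at least 10 CPM in 1 of the 2 libraries was set against 10000 random lists of the same size matched on mean expression in 20 bins. A list was called apart from them outside the 2.5 to 97.5 percentiles, and at least 5 members were needed. This describes these libraries and does not test between groups. Mx1, Atp5f1a, Atp5f1b, Atp5mc1 and Atp5pd were not among the genes measured. The covariance of the profiles used a pseudocount of 0.5 counts and 100 simulated pairs drawn at the observed depths from the pooled profile.

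The steps were tested on simulated data with 200 changed genes at the observed depths. In resident alveolar macrophage-like cells, 100% of genes changed 2-fold and 99% of those changed 1.75-fold were recovered for GW5074 (3699 genes), and 100% of both for KO (3750 genes). In monocyte-derived macrophage-like cells 100% were recovered in both comparisons (3393 and 3409 genes). No unchanged gene passed the size rule. The intervals covered the true ratio for 95.2% and 95.3% of genes in the first class and 95.1% and 95.4% in the other. Random lists were called apart in 4.0%, 2.5%, 5.5% and 5.0% of cases, and lists shifted by 0.3 in log2 in 100%. These draws hold counting noise only, not differences between pools.

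Alternatives covered the cell filter, doublets, clustering resolution, centring of each gene within its library before the principal components, scaling, weighting of cells, the minimum CPM and summing all cells. DESeq2 1.42.0 (median-of-ratios size factors) and edgeR 4.0.16 (TMM), in R 4.3.3, were used for scaling factors only. Against CPM, TMM or size factors moved the median of all genes by under 0.1 in the macrophage classes and by over 0.1 in some comparisons of the others. By CPM, TMM and size factors, the medians for KO over WT were −0.07, 0.07 and 0.07 in T cell-like and −0.08, 0.08 and 0.10 in migratory dendritic cell-like cells. For KO over GW5074 they were −0.04, 0.09 and 0.10 in T cell-like, −0.09, 0.03 and 0.04 in conventional dendritic cell 1-like, −0.03, 0.10 and 0.09 in conventional dendritic cell 2-like, −0.09, 0.04 and 0.05 in migratory dendritic cell-like and 0.17, 0.44 and 0.40 in neutrophil-like cells. In neutrophil-like cells for GW5074 they were −0.03, −0.27 and −0.17. Added after the data were seen were removal of the 10% of cells with the highest doublet scores, removal of the called doublets, a denominator without neutrophil-like cells, single clusters of the main class, and migratory dendritic cell-like cells without the cluster that came to over 90% from 1 library. B cell-like and plasmacytoid dendritic cell-like cells were too few for comparisons within class.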

Results

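Lavage cells from mice given bleomycin, an agent that injures the lung and is used to model pulmonary fibrosis, were profiled by droplet 3' single-cell RNA sequencing. Cells were taken 14 days after airway instillation from wild-type (WT) mice, from WT mice treated with GW5074, a small-molecule kinase inhibitor, and from knockout (KO) mice lacking Clec7a, the gene of the β-glucan receptor Dectin-1. The labels name DMSO, the vehicle, for the untreated WT and the KO samples. The lavage fluid of each group was pooled and sorted for CD11b+ or CD11c+ cells, so the data comprised 3 libraries, 1 library per group, and a difference between groups could not be separated from one between pools or runs. The WT DMSO library held 39180331 UMIs over 13504 barcodes, the WT GW5074 library 45462817 over 17809, and the KO DMSO library 34859676 over 11678. After filtering, 13454, 17792 and 11642 cells remained, with median depths of 2438.5, 2276 and 2937 UMIs and median mitochondrial shares of 1.41%, 2.34% and 2.18%. All intervals are 95% intervals and cover counting error only. No test between groups was possible, and "higher" and "lower" mean at least a 1.5-fold ratio whose interval excludes 1.

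Clec7a (ENSMUSG00000079293; mm10 chromosome 6, positions 129461591 to 129472779, minus strand) was examined first, since it should be lost in the KO library. In resident alveolar macrophage-like cells it was measured at 870 CPM (UMIs scaled to the class total, 845 to 895) in the WT DMSO library, 926 CPM (909 to 944) in the GW5074 library and 15.8 CPM (13.5 to 18.4) in the KO library. Monocyte-derived macrophage-like cells had 702, 750 and 12.6 CPM. A UMI of Clec7a was found in 83.4%, 80.0% and 4.35% of resident alveolar macrophage-like cells, and in 52.6%, 56.1% and 1.46% after thinning each cell to 1000 UMIs, which left out 26, 103 and 74 cells. T cell-like cells, which should lack the receptor, served as background. They showed a Clec7a UMI in 6.24% of cells in the WT DMSO library and 6.05% in the GW5074 library at median depths of 1097 and 684 UMIs. After thinning, which left out 179 and 323 cells, these shares were 5.51% and 14.0%. In the KO library 0 of 348 T cell-like cells, at a median of 1010.5 UMIs, had a Clec7a UMI. The exons deleted in the KO mice were not stated. A 3' tag may lie outside a deletion, so the low tag count shows loss of the 3' transcript end and not which exons were removed.

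The makeup of the lavage differed between the WT DMSO library and both other libraries. Neutrophil-like cells made up 22.3% (21.6 to 23.0) of kept cells in the WT DMSO library, 0.629% (0.519 to 0.757) in the GW5074 library and 2.26% (2.0 to 2.55) in the KO library, 35.4-fold and 9.86-fold lower. With at least 500 genes and at most 10% mitochondrial UMIs per cell, called the stricter cell filter below, these log2 ratios went from −5.14 and −3.30 to −4.01 and −4.13, so the order of both libraries turned. That of GW5074 was also −4.23 at Leiden resolution 0.5 and −4.18 without called doublets (4 cells left out and the rest clustered anew), and that of KO −3.93 at resolution 2. Resident alveolar macrophage-like cells made up 11.5%, 27.4% and 31.2%, and monocyte-derived macrophage-like cells 11.8%, 29.4% and 27.4%. Together both macrophage classes were 23.2% (22.5 to 24.0) of the WT DMSO library, 56.8% (56.1 to 57.6) of the GW5074 library and 58.6% (57.7 to 59.5) of the KO library, with log2 ratios that went from 1.29 and 1.33 to 2.93 and 2.93 when each gene was centred within its library before clustering. Migratory dendritic cell-like cells were 1.59-fold lower with GW5074 and 1.62-fold lower in the KO library, at 24.2%, 15.2% and 14.9%. That difference lay in cluster 10 (9.64%, 0.0731% and 0.00859%, the last from 1 cell), while clusters 1 (8.96%, 9.65% and 9.29%) and 6 (5.60%, 5.52% and 5.65%) of this class differed little. B cell-like cells were 4.75-fold and 4.88-fold lower, at 2.43%, 0.511% and 0.498%. T cell-like cells made up 3.22%, 2.14% and 2.99% and were 1.51-fold lower with GW5074, at the edge of the size rule. Without the 10% highest doublet scores the T cell-like log2 ratio for GW5074 was −0.15, and those of migratory dendritic cell-like cells were −0.54 and −0.58, all short of the rule. The T cell-like ratio was also short of the rule under centring within libraries (−0.58). Under the stricter filter the T cell-like ratio lay further from 0 (−1.68). That filter drops cells with few genes, and T cell-like cells were shallower with GW5074 (medians of 684 against 1097 UMIs). Shares of conventional dendritic cell 1-like cells (3.99%, 4.51% and 5.05%), conventional dendritic cell 2-like cells (2.56%, 2.25% and 2.05%) and plasmacytoid dendritic cell-like cells (0.223%, 0.163% and 0.180%) stayed within 1.5-fold of the WT DMSO library.

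**Figure D1:**
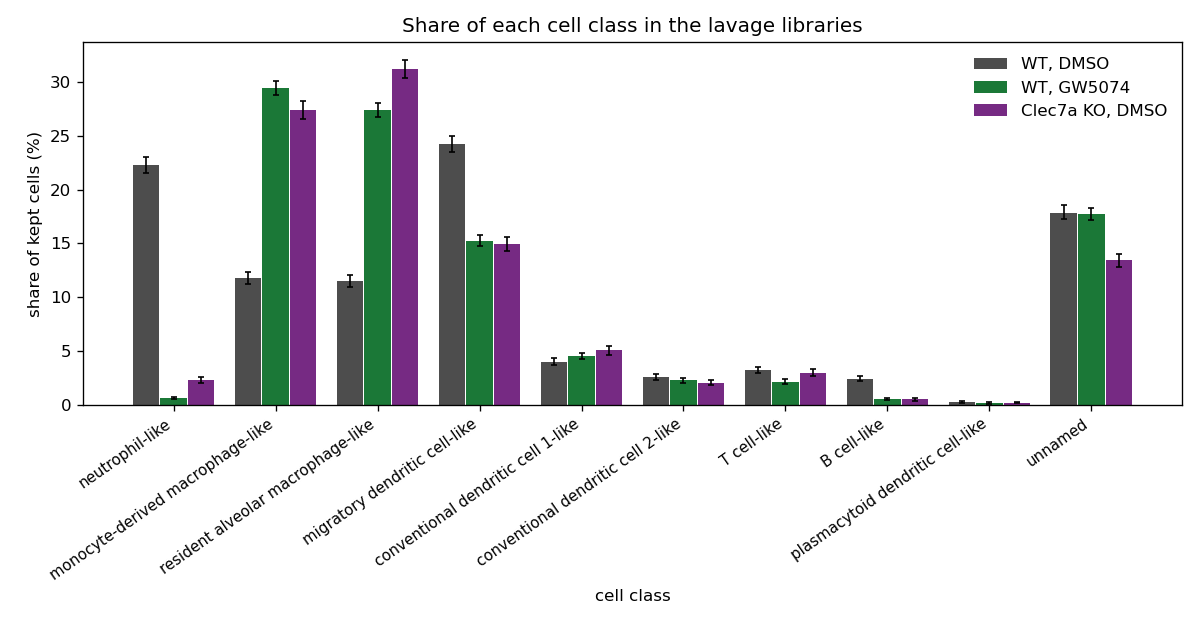
Share of kept cells (percent, y axis) of each cell class in the 3 libraries, with exact binomial 95% intervals that cover counting error only. Neutrophil-like cells stand at 22.3% in the WT DMSO library against 0.629% and 2.26%, and each macrophage class is below 12% there and above 27% in the other libraries.

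Shares sum to a whole, so a lower neutrophil-like share raises the others. With neutrophil-like cells left out of the denominator, the log2 ratio of both macrophage classes went from 1.29 to 0.94 for GW5074 and from 1.33 to 1.0 for the KO library. Shares also depend on the sort for CD11b or CD11c, on the minimum of 500 UMIs of every deposited barcode and on depth. Neutrophil-like cells lie close to that minimum, with median depths of 638, 560.5 and 599 UMIs. Depth in resident alveolar macrophage-like cells was 3238, 2274 and 2837 UMIs. Unnamed clusters held 17.9%, 17.7% and 13.4% of cells. Of these, a cluster with Vcan, Lcn2 and Arg1 among its leading genes held 7.92% of WT DMSO, 0.972% of GW5074 and 0.515% of KO cells. With all unnamed cells counted as macrophages, the combined share was 41.1%, 74.6% and 72.0%.

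To see what GW5074 did within a cell class, counts were summed over the 1546 and 4875 resident alveolar macrophage-like cells of the WT DMSO and WT GW5074 libraries. Arg1, which encodes arginase 1 and marks alternatively activated macrophages, was 2.64-fold lower with GW5074 (2.40 to 2.90), at 68.8 against 182 CPM. This fell short of the size rule when each gene was centred within its library before clustering (log2 ratio −0.23) and in cluster 3 alone (−0.55). Arg1 is also among the leading genes of an unnamed cluster with 7.92% of WT DMSO, 0.972% of GW5074 and 0.515% of KO cells. Whether RNA or cells of that cluster add to Arg1 in the macrophage classes, here and below, was not tested. Dusp1, a phosphatase that inactivates MAP kinases, was 1.77-fold lower (1.51 to 2.07). Fkbp5 and Klf9, both induced by glucocorticoids, were 1.76-fold (1.56 to 1.97) and 1.57-fold lower. Also lower were Srgn, the granule proteoglycan serglycin, by 1.64-fold, Klhl6 by 1.60-fold, Utp18 by 1.56-fold, Ndufb4 by 1.52-fold and Phlda3 by 1.51-fold. Of these, Phlda3 fell short of the rule in 8 alternatives, both scalings included (−0.58 to −0.45), Klf9 at Leiden resolution 2 (−0.58) and in cluster 0 alone (−0.39), Ndufb4 under the stricter cell filter (−0.58) and in cluster 0 alone (−0.48), Klhl6 in cluster 0 alone (−0.44) and Utp18 without the highest doublet scores (−0.58). Slco2b1 was at a ratio of 1.44-fold below WT DMSO, short of the size rule. Mamdc2 was 2.29-fold higher (1.88 to 2.81), Tppp3 1.92-fold, Lars2, the mitochondrial leucyl-tRNA synthetase, 1.73-fold and Ndufs5 1.55-fold, the last short of the rule in 4 alternatives (0.47 to 0.58). Others lay further from 0 in some settings, under centring Dusp1 (−1.91), Fkbp5 (−1.87), Klf9 (−1.51), Srgn (−1.94) and Klhl6 (−1.73), without called doublets Arg1 (−2.10), and in cluster 3 alone Mamdc2 (1.92) and Tppp3 (1.56). Pdlim1 stood 1.5-fold above WT DMSO, just under the rule. Krt19, Cd2, Htr2c and Kcnip4 were 2.13-fold, 1.93-fold, 1.83-fold and 1.69-fold higher, but these 4 reversed under the same centring, and Krt19 in cluster 0 (0.43), Htr2c (0.40) and Kcnip4 (0.30) in cluster 3 fell short of the rule. Krt19, Htr2c and Kcnip4 lead cluster 3, which made up 24.8% of the class in the WT DMSO library and 33.8% in the GW5074 library.

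Of 21 gene lists with enough measured members, 5 had a median outside the central 95% of expression-matched random lists in resident alveolar macrophage-like cells. The type I interferon response was above it, with a median log2 ratio of 0.30 and 9 of 11 members above 0. Oas1a and Zbp1, sensors of viral nucleic acid, were 1.79-fold and 1.63-fold higher, but Oas1a fell to 0.24 under centring and 0.15 in cluster 3 alone, and Zbp1 fell short of the rule in 5 alternatives (0.37 to 0.58). Matrix remodelling genes had a median of 0.15 (10 of 13 above 0), led by the elastase gene Mmp12, 3.07-fold higher (2.39 to 3.99) and at 2.51 in cluster 3 alone. Mmp12, like Ccl9 below, is among the leading genes of cluster 4 of the monocyte-derived class. That cluster held 4.44% of WT DMSO, 9.90% of GW5074 and 10.0% of KO cells, and whether its RNA adds to both genes here was not tested. The collagenase gene Mmp14 stood 1.32-fold above WT DMSO, and went from 0.41 to 1.56 under centring. Chemokines and their receptors had a median of 0.15 (7 of 11 above 0), with Ccl9 1.47-fold above and Cxcl2 1.95-fold lower. In cluster 3 alone both were level (log2 ratios of −0.01 and −0.04), and Cxcl2 was at −0.45 without called doublets and −1.52 under centring. Cholesterol synthesis genes had a median of −0.22, with 15 of 18 members below 0, among them Insig1 (1.37-fold below) and Dhcr7 (1.32-fold below). Dissociation and heat shock genes had a median of −0.13 (13 of 17 below 0), with the immediate early genes Egr1 2.19-fold lower (−2.86 under centring) and Zfp36 1.44-fold below. When all kept cells were summed without classes, the chemokine and cholesterol synthesis medians reversed. In this class S100a8, an abundant neutrophil transcript, was at 497 CPM in the WT DMSO library and 196 CPM in the GW5074 library, and S100a9, another, at 181 and 31.3 CPM.

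MEK-ERK targets, genes induced by this kinase pathway, had a median of −0.08 over 7 members, inside the random range of −0.19 to 0.17. Of the members, Ier3 was 1.98-fold lower (−2.61 under centring). Egr1, named above with the heat shock genes, is also a member and was lower (log2 ratios of −1.26 in cluster 0 alone and −0.96 in cluster 3 alone). The profibrotic macrophage list had a median of 0.05 (9 of 17 above 0). Its members went both ways. Spp1, which encodes osteopontin, stood 1.33-fold below WT DMSO and reversed when genes were centred within libraries. Mmp12 and Mmp14, named above with matrix remodelling, are also members and were above WT DMSO, Mmp12 with log2 ratios of 1.57 in cluster 0 alone and 2.51 in cluster 3 alone. Medians were also inside the random range for Dectin-1 signalling (−0.07), alternative activation (−0.08), inflammatory cytokines (−0.06), the interferon gamma response (0.02), MHC class II (0.09), lipid handling (0.01), glycolysis (−0.02), oxidative phosphorylation (−0.06), lysosome (0.01), efferocytosis (−0.03), NRF2 (−0.07), eicosanoids (−0.02), the unfolded protein response (0.07) and the neighbours of Clec7a (0.11). Not all stayed inside: under centring the profibrotic list (0.29), alternative activation (−0.27), MEK-ERK targets (−0.35), inflammatory cytokines (−0.71), MHC class II (0.71) and efferocytosis (0.14) were outside, and inflammatory cytokines also in 4 other alternatives. Of the lipid handling genes, the cholesterol exporter Abca1 was 1.57-fold higher, which reversed under the same centring and fell short of the rule in 3 other alternatives (0.37 to 0.47). Cycling genes, aryl hydrocarbon receptor targets and the list for free RNA of epithelium and red cells had fewer than 5 measured members in both macrophage classes and were not tested there.

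In monocyte-derived macrophage-like cells (1582 and 5238 cells), Arg1 was 2.95-fold lower with GW5074 (2.79 to 3.13), at 125 against 369 CPM, with a log2 ratio of −1.56 that went to −0.88 under centring. Fkbp5 (1.92-fold), Dusp1 (1.87-fold) and Klhl6 (1.72-fold) were lower as in the other macrophage class. Thbs1, which encodes the matrix protein thrombospondin 1, was 1.92-fold lower (1.72 to 2.13). Under centring Fkbp5 (−1.87), Dusp1 (−2.11), Klhl6 (−2.20) and Thbs1 (−1.81) lay further from 0. Thbs1 leads cluster 7, which held 20.2% of the class in the WT DMSO library and 23.9% with GW5074. Lars2 was 1.91-fold and the complement gene C3 1.64-fold higher, C3 at a log2 ratio of 0.46 under centring. Kcnip4 was 1.91-fold higher but reversed under centring and was at 0.54 without the highest doublet scores, and Vwf and Aoah stood 1.47-fold and 1.45-fold above WT DMSO. Inflammatory cytokines and NF-kB targets had a median of −0.30, with 13 of 16 members below 0, and chemokines one of −0.22 (12 of 16). The neutrophil-attracting chemokine gene Cxcl2, in both lists, was 2.15-fold lower (1.78 to 2.60), and at −2.04 under centring. Dissociation and heat shock genes had a median of −0.21 (14 of 17 below 0), with Egr1 1.5-fold lower, short of the rule in 5 alternatives, both scalings included (−0.58 to −0.37), but at −2.31 under centring. Lysosome genes had a median of 0.12, with 20 of 22 above 0. Type I interferon genes had a median of 0.21 (18 of 23 above 0, Oas1a 1.53-fold higher), which reversed under centring, where Oas1a was at 0.19 (0.52 as a mean of CPM per cell and 0.56 without called doublets). Interferon-induced genes lead cluster 18, 5.12% of the class in the WT DMSO library and 5.50% in the GW5074 library. MEK-ERK targets, which include Egr1, had a median of −0.14 with 7 of 8 members below 0. This median was at percentile 2.57 of random lists and so just inside the central 95%, but outside it in 5 alternatives (−0.82 to −0.23). Under centring the inflammatory median was −1.12, and the interferon gamma response (−1.12) and the profibrotic list (0.34) were among further lists outside the range. Clusters 4 and 2 were nearly level in the WT DMSO library, at 37.7% and 37.0% of the class. Cluster 2 was likewise at 37.0% with GW5074 and at 42.8% in the KO library, and cluster 4 at 33.6% and 36.7%. S100a8 was at 627 CPM in the WT DMSO class and 238 CPM with GW5074, and S100a9 at 255 and 51.9 CPM.

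**Figure D2:**
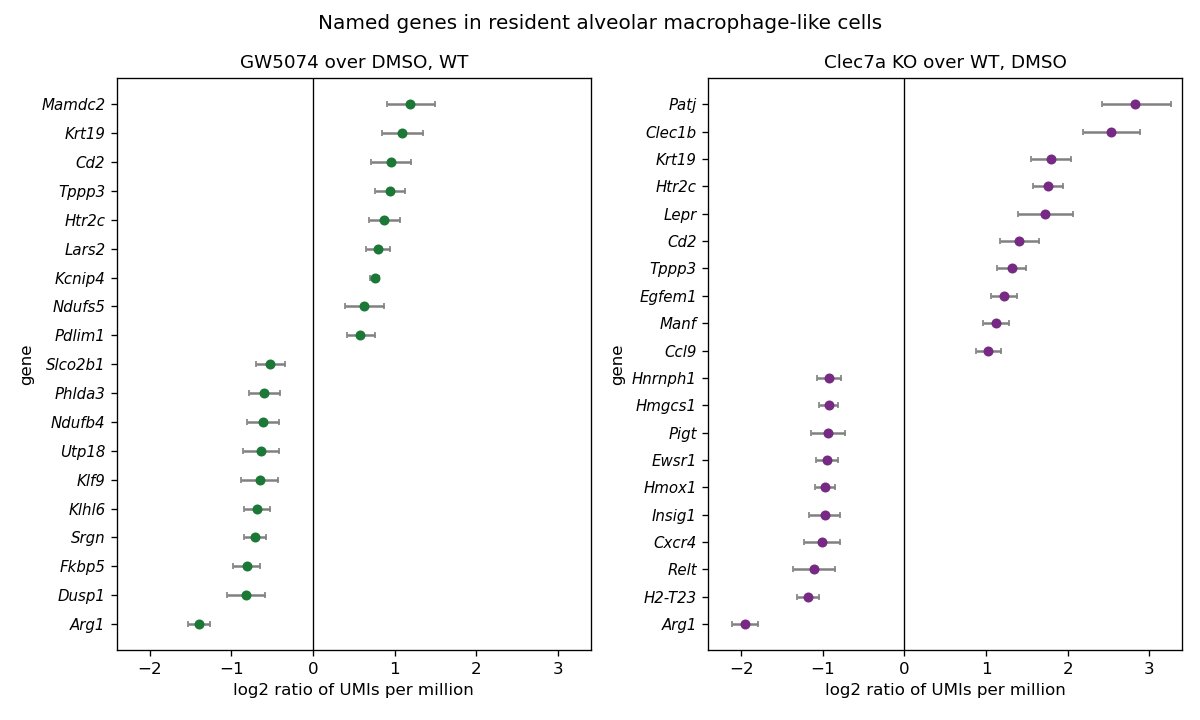
Log2 ratio (x axis) of named genes (y axis) in resident alveolar macrophage-like cells for GW5074 over DMSO in WT and for KO over WT under DMSO, with 95% intervals of counting error. Arg1 is below 0 in both panels, at −1.40 and −1.96, and Patj and Clec1b reach 2.83 and 2.53 in KO resident alveolar macrophage-like cells.

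In the other classes, GW5074 was compared at lower depth. Fkbp5 was lower in T cell-like cells by 3.56-fold (2.02 to 6.78), in conventional dendritic cell 2-like cells by 5.98-fold, in migratory dendritic cell-like cells by 3.13-fold and in neutrophil-like cells by 4.28-fold. Klhl6 was 5.80-fold lower in conventional dendritic cell 2-like and 16.7-fold lower (10.2 to 29.5) in migratory dendritic cell-like cells. In the latter it remained lower without cluster 10 (log2 ratio −4.02 against −4.07), and at −3.10 without the 10% highest doublet scores. That cluster held 39.8% of the class in the WT DMSO library, while cluster 1 held 63.3% with GW5074 and 62.1% in the KO library. Ddit4, which leads cluster 10, was 7.81-fold lower in migratory dendritic cell-like cells and had a log2 ratio of −0.47 without it. The chemokine gene Ccl4 was 2.51-fold lower in T cell-like cells, a log2 ratio of −1.33 that went to −0.65 under the stricter cell filter, and Gsr and Ppdpf were 2.07-fold and 1.82-fold lower in conventional dendritic cell 1-like cells, but without the 10% highest doublet scores Gsr had a log2 ratio of −0.46, short of the rule. The interferon-inducible genes Ifi27l2a and Slfn5 were 3.36-fold and 2.69-fold higher in conventional dendritic cell 2-like cells. Lyz2, an abundant macrophage transcript, was 2.42-fold higher in T cell-like, 2.63-fold in conventional dendritic cell 1-like and 2.77-fold in migratory dendritic cell-like cells. Ctsd, a lysosomal protease that macrophages also express highly, was 2.26-fold and 2.14-fold higher in the latter classes. Whether free RNA of macrophages adds to the higher Lyz2 and Ctsd was not tested. H2-Aa was 2.17-fold higher in T cell-like cells, where Leiden resolution 0.5 gave log2 ratios of 0.11 for it and 0.51 for Lyz2 (0.52 at resolution 2, 0.68 under centring). Neutrophil-like cells with GW5074 numbered 112. In them Gpnmb was 6.27-fold and Specc1 4.98-fold higher, but with at least 500 genes and at most 10% mitochondrial UMIs per cell their log2 ratios were 0.44 and 0.27, short of the rule, as was Specc1 at resolution 0.5 (0.58) and without called doublets (0.55), where Gpnmb was at 0.72 and 0.66. Bcl2l15, a leading gene of this cluster, and Prnp were 33.3-fold (5.96 to 1317) and 15.8-fold (2.83 to 627) lower, each from 1 UMI, with Bcl2l15 at a log2 ratio of −6.58 without called doublets. With so little of a leading gene, these 112 cells may not be the same kind of cell as in the WT DMSO library, which was not tested. S100a8 in migratory dendritic cell-like cells was at 839 CPM in the WT DMSO library and 84.7 CPM with GW5074, in T cell-like cells at 2229 and 451 CPM, in conventional dendritic cell 1-like cells at 515 and 92.0 CPM and in conventional dendritic cell 2-like cells at 1045 and 101 CPM.

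The effect of losing Clec7a was examined by comparing the KO and WT libraries under DMSO. In resident alveolar macrophage-like cells (3635 and 1546 cells), Arg1 was 3.88-fold lower in the KO library (3.48 to 4.34), at 46.7 against 182 CPM, and had a log2 ratio of −0.79 under centring and −2.54 at Leiden resolution 0.5 against −1.96. H2-T23, a nonclassical MHC class I gene, was 2.27-fold lower (2.07 to 2.49), the receptor gene Relt 2.15-fold and the chemokine receptor gene Cxcr4 2.01-fold. Insig1 and Hmgcs1, genes of sterol regulation and synthesis, were 1.97-fold and 1.90-fold lower, and the haem oxygenase gene Hmox1 1.96-fold. Genes of RNA binding proteins, Ewsr1 and Hnrnph1, were 1.93-fold and 1.89-fold lower, as was Pigt, of glycolipid anchor assembly, by 1.91-fold. Patj, a polarity scaffold gene on chromosome 4 (98395785 to 98719603), was 7.10-fold higher (5.36 to 9.60), at 68.8 against 9.69 CPM, a log2 ratio of 2.83 that fell to 0.96 under centring and 2.08 in cluster 3 alone. In monocyte-derived macrophage-like cells Patj did not differ beyond counting error (1.01-fold below, with 25 and 16 UMIs). Clec1b, encoding the C-type lectin CLEC-2, was 5.76-fold higher (4.54 to 7.41). Manf, a secreted endoplasmic reticulum stress protein, was 2.17-fold higher, Tppp3 2.48-fold, Cd2 2.65-fold and Ccl9 2.04-fold. Krt19, Htr2c, Lepr and Egfem1 were 3.47-fold, 3.38-fold, 3.29-fold and 2.33-fold higher, but all 4 reversed under centring, where Cd2 fell short of the rule (0.40). Krt19, Htr2c and Lepr lead cluster 3, which was 24.8% of the class in the WT DMSO library and 44.0% in the KO library. Within cluster 0 alone Egfem1 also reversed, while Krt19 had a log2 ratio of 1.79, Htr2c one of 0.71 and Lepr one of 2.48. In cluster 3 alone those of Krt19, Htr2c and Lepr were 1.05, 1.02 and 0.94, and Insig1 (−1.56) and Tppp3 (1.91) lay further from 0.

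Of 21 lists, 8 lay outside the random range in KO resident alveolar macrophage-like cells. The neighbours of Clec7a on chromosome 6 had a median log2 ratio of 0.47, with 8 of 8 measured members above 0 and no random list as high, but with all kept cells summed the median was 0.06, inside the range. Clec1a, whose gene body (129424772 to 129452000) is adjacent to Clec7a, was 8.01-fold higher (5.15 to 13.1), a log2 ratio of 3.0 that was 2.2 in cluster 3 alone. Cholesterol synthesis genes had a median of −0.49, with 17 of 18 members below 0. Eicosanoid genes had a median of −0.29 (11 of 13 below 0), with the cyclooxygenase gene Ptgs1 1.7-fold and the prostaglandin receptor gene Ptger4 1.61-fold lower. Lysosome genes had a median of −0.15 (17 of 22 below 0), with the saposin precursor gene Psap 1.64-fold and the protease gene Lgmn 1.59-fold lower. The interferon gamma response had a median of −0.33 with 6 of 9 members below 0, and its members went both ways, Irf1 1.51-fold lower and Gbp7 1.74-fold higher. The unfolded protein response had a median of 0.21 (9 of 11 above 0), with the chaperone gene Hspa5 1.70-fold and Sdf2l1 1.55-fold higher but Atf4 1.67-fold lower. Type I interferon genes had a median of 0.21 (8 of 12 above 0), with Ifi211 1.97-fold and Oas1a 1.7-fold higher. This median reversed when only genes of at least 50 CPM were used. In cluster 3 alone Ifi211 was at 2.52 and Oas1a reversed, and without called doublets Oas1a was at 0.58. Chemokines had a median of 0.21, with 6 of 11 above 0 and Cxcl2 2.03-fold higher, and this median reversed under centring. Summing all kept cells without classes reversed the medians of cholesterol synthesis, lysosome and chemokine genes. Among the named members, these fell short of the rule: Ptgs1 (−0.52), Psap (−0.45), Oas1a (0.16) and Cxcl2 (0.33) under centring, Ptger4 in 3 alternatives (−0.53 to −0.13), Lgmn in 2 (−0.55 and −0.53), Irf1 in 6 (−0.56 to −0.49) and Sdf2l1 in 3 (0.45 to 0.54). Lysosome genes remained outside the random range in 4 of 10 alternatives, chemokines in 5 of 10, the interferon gamma response in 5 of 9 and type I interferon genes in 7 of 10. S100a8 in this class was at 497 CPM in the WT DMSO library and 254 CPM in the KO library, and S100a9 at 181 and 15.6 CPM.

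Lists tied to the receptor or to fibrosis lay inside the random range in KO resident alveolar macrophage-like cells. Dectin-1 signalling had a median of −0.16 with 18 of 23 members below 0, at percentile 3.64. Its members Prkcd, the kinase downstream of the receptor, Egr2 and Il1b were 1.76-fold, 1.79-fold and 1.71-fold lower. Il1b was short of the rule without called doublets (−0.55) and in cluster 0 alone (−0.46) but at −1.61 under centring. Cxcl2, also a member, went the other way, with a log2 ratio of 1.02 that was 0.33 under centring. Whether free RNA of other cells adds to Il1b in this class was not tested. The medians were −0.03 for the profibrotic macrophage list, −0.03 for matrix remodelling, −0.13 for alternative activation, 0.16 for MEK-ERK targets and −0.00 for inflammatory cytokines. Those of the profibrotic list and of MEK-ERK targets reversed under centring, and both reversed, with matrix remodelling, when all kept cells were summed. Outside the range under centring were the profibrotic list (0.30), MEK-ERK targets (−0.49), alternative activation (−0.65), inflammatory cytokines (−0.48), MHC class II (0.73) and NRF2 (−0.31), and Dectin-1 signalling was outside it in 3 other alternatives (−0.51 to −0.18). With each cell weighted alike, MEK-ERK targets were above the range (0.22). Mmp12 was 2.09-fold higher (2.32 in cluster 3 alone), Abca1 1.78-fold and the glycolytic gene Gapdh 1.66-fold, but Abca1 was at 0.14 under centring and 0.52 in cluster 0 alone, and Gapdh at 0.52 without called doublets. Spp1 stood 1.49-fold below WT and reversed under centring. Of the heat shock genes, Hspa8 and Hsph1 were 1.93-fold and 1.73-fold higher (Hsph1 at 0.47 in cluster 0 alone and 1.39 in cluster 3 alone), at a list median of 0.03. That median was above the range at a minimum of 50 CPM (0.19) and without called doublets (0.19). The remaining medians were 0.01 for MHC class II, 0.05 for lipid handling, −0.08 for glycolysis, −0.13 for oxidative phosphorylation (20 of 22 below 0), −0.19 for efferocytosis and −0.06 for NRF2. Efferocytosis was outside the range in 4 alternatives, below it at −0.29 without the highest doublet scores but above it at 0.19 with all kept cells summed. Oxidative phosphorylation was below it in 2 (−0.22 and −0.14).

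In KO monocyte-derived macrophage-like cells (3188 against 1582 cells), Arg1 was 3.97-fold lower (3.70 to 4.26) and Thbs1 3.30-fold lower (2.87 to 3.80), the latter at −2.72 under centring. Cluster 7, which Thbs1 leads, held 20.2% of the class in the WT DMSO and 14.7% in the KO library. Cxcr4, Nav2 and H2-T23 were 2.0-fold, 2.0-fold and 1.94-fold lower. Olr1, the oxidised LDL receptor gene that lies next to Clec7a (129485244 to 129507165), was 2.19-fold higher (2.06 to 2.32). Manf, the phospholipase gene Plaat3 and Hspa8 were 2.0-fold, 1.81-fold and 1.79-fold higher, Plaat3 short of the rule under centring (0.42). Cxcl2 was 1.86-fold higher but reversed under centring. The neighbours of Clec7a had a median of 0.53, with 8 of 9 members above 0, Clec1a 21.9-fold higher (12.9 to 40.3) and Clec1b 4.36-fold. Their log2 ratios of 4.45 and 2.12 were 5.09 with each cell weighted alike and 2.95 under centring. MHC class II genes had a median of 0.22 (8 of 11 above 0) and the unfolded protein response one of 0.17 (9 of 11), with Hspa5 1.61-fold and Sdf2l1 1.54-fold higher. Matrix remodelling genes had a median of −0.20 (11 of 14 below 0), with Tgfbi 1.64-fold lower, and oxidative phosphorylation one of −0.19 (20 of 22 below 0). Type I interferon, heat shock and inflammatory genes had medians of 0.12, 0.12 and 0.11, above random lists, and all 3 reversed under centring. Oas1a was 1.60-fold higher and Psap 1.53-fold lower. Under centring Tgfbi (−0.52), Oas1a (0.20) and Psap (−0.42) fell short of the rule, as did Psap by both scalings (−0.55) and Oas1a without the highest doublet scores (0.58). Medians inside the random range included −0.04 for Dectin-1 signalling, −0.08 for the profibrotic list, −0.14 for alternative activation and −0.20 for MEK-ERK targets (7 of 8 below 0), all 4 outside it under centring (−0.38, 0.25, −0.75 and −0.97). S100a8 in this class was at 627 CPM in the WT DMSO and 250 CPM in the KO library, and S100a9 at 255 and 42.3 CPM.

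**Figure D3:**
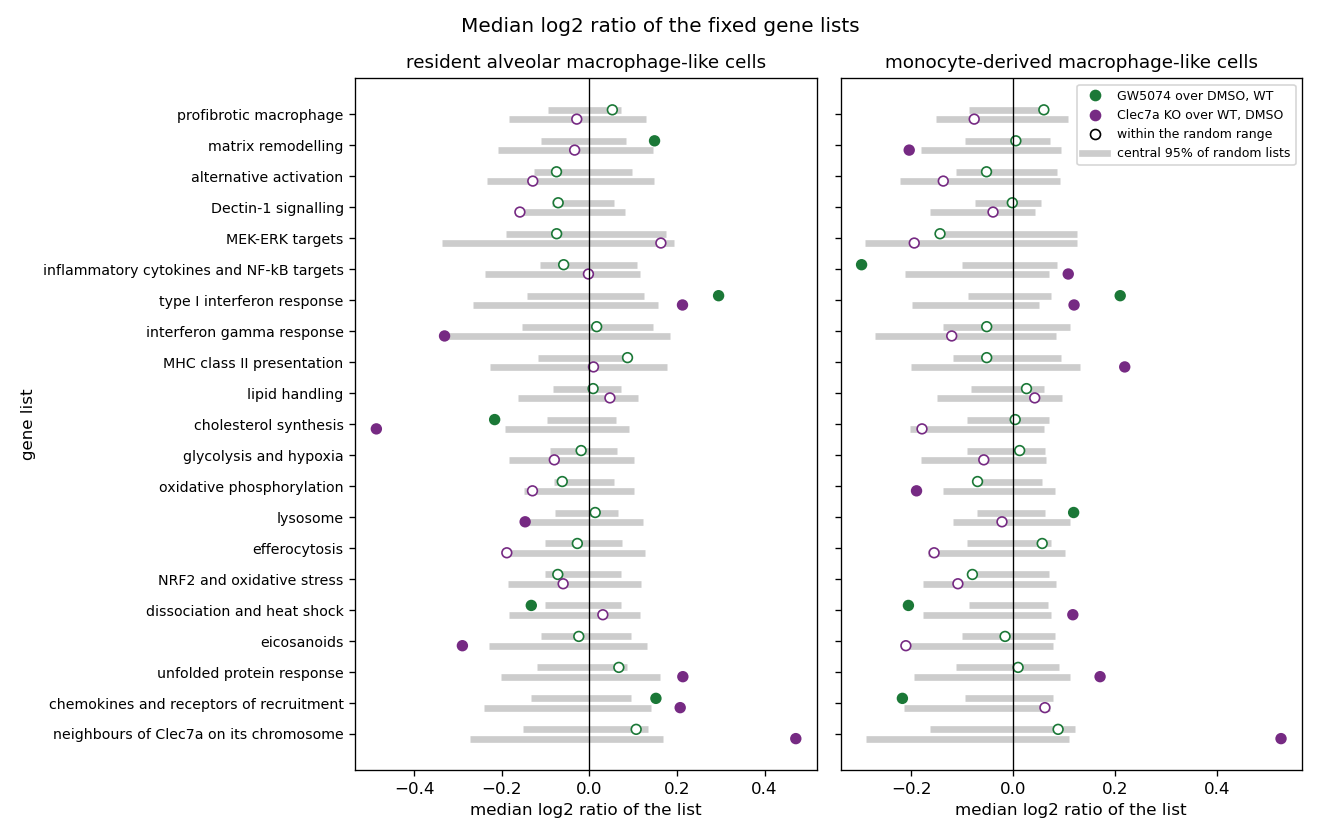
Median log2 ratio (x axis) of each fixed gene list (y axis) in the macrophage classes, green for GW5074 over DMSO and purple for KO over WT, with grey bars for the central 95% of expression-matched random lists and filled points outside them. Neighbours of Clec7a lie at 0.47 and 0.53 in the KO comparison, and cholesterol synthesis lies at −0.22 and −0.49 in resident alveolar macrophage-like cells.

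In the remaining classes of the KO library, H2-T23 was 3.15-fold lower (2.74 to 3.63) in conventional dendritic cell 1-like cells. The cytokine gene Il1b was 3.67-fold lower there and 8.84-fold lower (4.49 to 19.8) in T cell-like cells, where Ccl4 was 14.1-fold lower (6.64 to 35.6). Without the 10% highest doublet scores the log2 ratio of Il1b in T cell-like cells went from −3.14 to −1.63. Migratory dendritic cell-like cells had lower Klhl6 (10.3-fold) and Cirbp (5.92-fold), and higher Il12rb2 (3.29-fold) and the chaperone gene Hsp90aa1 (2.81-fold). Without cluster 10, the log2 ratios of Klhl6, Cirbp, Il12rb2 and Hsp90aa1 were −3.32, −1.54, 1.71 and 1.16, and without the 10% highest doublet scores that of Klhl6 was −2.46. Prnp and Ramp3 were 5.09-fold and 4.98-fold lower in conventional dendritic cell 2-like cells (log2 ratios of −2.95 and −3.40 at Leiden resolution 2), where H2-Q7 was 3.14-fold higher. Mreg was 3.15-fold higher in that class, but Leiden resolution 2 gave a log2 ratio of 0.02. Pcdh7 and Gpr183 were 4.37-fold and 2.76-fold higher in conventional dendritic cell 1-like cells, and Cmss1 and Ubb 2.78-fold and 2.76-fold higher in T cell-like cells. Among 263 neutrophil-like cells of the KO library, the interferon-induced gene Rsad2 was 7.12-fold higher (4.60 to 10.9). Bpifa1, an airway secretory gene, was 671-fold higher (337 to 1564), but its 424 UMIs came from 3 cells, and its log2 ratio of 9.39 fell to 2.92 under centring and 3.02 without the 10% highest doublet scores. Cstdc4 and Bcl2l15, which lead this cluster, were 38.6-fold lower (13.2 to 188, from 3 UMIs) and at least 28.2-fold lower (0 UMIs, floor of 3 counts for the class), with log2 ratios of −4.12 and −3.73 under the stricter cell filter. Here too, whether the class holds the same kind of cell in both libraries was not tested. S100a8 in migratory dendritic cell-like and T cell-like cells was at 48.5 and 122 CPM in the KO library against 839 and 2229 CPM in the WT DMSO library, and in conventional dendritic cell 1-like and 2-like cells at 74.4 and 142 against 515 and 1045 CPM. Whether free RNA of other cells adds to the lower ratios in these classes, such as that of Il1b, was not tested.

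The KO and GW5074 libraries were also compared directly, without the shared WT DMSO library. Neutrophil-like cells were 3.59-fold higher in the KO library, but this log2 ratio of 1.84 turned to −0.12 under the stricter cell filter and was 0.81 at Leiden resolution 0.5 and 0.80 without called doublets. Both macrophage classes together differed by 1.03-fold. Of 21 lists, 10 lay outside the random range in each macrophage class. In resident alveolar macrophage-like cells of the KO library, cholesterol synthesis (−0.33), the interferon gamma response (−0.33), efferocytosis (−0.22), lysosome (−0.19) and oxidative phosphorylation (−0.15) were below it. Heat shock genes (0.22), MEK-ERK targets (0.19), inflammatory cytokines (0.18), lipid handling (0.16) and the neighbours of Clec7a (0.51) were above it. In monocyte-derived macrophage-like cells, inflammatory cytokines were above it with a median of 0.43 (12 of 16 above 0), as were heat shock genes (0.23), MHC class II (0.22), the unfolded protein response (0.18), chemokines (0.13) and the neighbours of Clec7a (0.55). Eicosanoids (−0.21), matrix remodelling (−0.20), cholesterol synthesis (−0.20) and lysosome (−0.16) were below it. Eicosanoids and cholesterol synthesis remained so in 4 of 9 alternatives each. In resident alveolar macrophage-like cells MEK-ERK targets remained outside in 5 of 9, the interferon gamma response in 6 of 9 and oxidative phosphorylation in 6 of 10. At a minimum of 50 CPM the inflammatory median in resident alveolar macrophage-like cells and the chemokine median in monocyte-derived macrophage-like cells reversed, as did the interferon gamma median with all kept cells summed.

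Both comparisons against WT DMSO share that library, which raises the covariance of their log2 ratios even without an effect. Across 8427 genes in resident alveolar macrophage-like cells the covariance was 0.0419 with r = 0.54, against a median of 0.0133 (0.0124 to 0.0144) and r = 0.68 in 100 simulated pairs of unchanged libraries. In monocyte-derived macrophage-like cells it was 0.0276 with r = 0.42 over 8275 genes, against 0.00988 and r = 0.65. In migratory dendritic cell-like cells it was 0.160 with r = 0.66 over 7931 genes, against 0.00813 and r = 0.31. The covariances, not the r values, can be set against each other. The control library could not be split, so part of the excess may come from it, and genes are not independent replicates. The spread of log2 ratios was wider for the KO library, with 95% of 3750 genes between −0.63 and 0.58 in resident alveolar macrophage-like cells, against −0.31 to 0.29 over 3699 genes for GW5074.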

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

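The tests of free RNA, of the compound alone, of the chromosome segment and of a general difference between libraries were chosen after the results were seen, those of the UMI minimum and of glucocorticoid targets before. Clusters left out of the named classes were looked at because their share of kept cells in a library exceeded that in the WT DMSO library, outside the comparisons above. Cluster 9, with Gm48099, Kcnip4 and mitochondrial transcripts among its leading genes, made up 5.47% of the GW5074 library against 2.94% of the WT DMSO library. Cluster 16, led by the mitotic genes Cdc20, Cenpf and Hmmr and otherwise resident alveolar macrophage-like, made up 2.33% with GW5074 and 2.03% in the KO library against 0.937%. Clusters of high doublet scores were also larger with GW5074, cluster 15 (migratory dendritic cell genes) at 2.80% against 1.51%, cluster 17 (conventional dendritic cell 1 genes) at 2.11% against 1.09% and cluster 20 (T cell genes) at 1.07% against 0.691%. Cluster 21, led by Rgcc, Gstm1 and the ferritin genes Fth1 and Ftl1, made up 0.842% of the KO library against 0.126% of the WT DMSO and 0.107% of the GW5074 library. No explanation was tested for these clusters.

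Neutrophil-like cells were far fewer in the GW5074 and KO libraries, and these cells sit near the 500-UMI minimum of the deposited barcodes, so a shallower library may lose them. The depth factor was the lowest ratio of median UMIs among 4 classes whose medians lay well above that minimum in every library. For GW5074 it was that of conventional dendritic cell 1-like cells (2318 against 4207 UMIs). Conventional dendritic cell 2-like cells, left out as closer to the minimum, differed more (1422 against 2777.5 UMIs), and a lower factor was not tried. In resident alveolar macrophage-like cells depth differed less (2274 against 3238 UMIs). Thinning the WT DMSO cells by the factor for the GW5074 library (0.551) and keeping those with at least 500 UMIs left 4.40% neutrophil-like cells, 6.99-fold over the 0.629% seen there and above the bound of 1.14%. Thinning by the factor for the KO library (0.814) left 14.3%, 6.32-fold over the 2.26% seen, with a bound of 3.82%. Both values argue against the minimum as the whole cause. From 22.3% in the WT DMSO library, and at these factors, the minimum may account for much of the drop with GW5074 and less of that in the KO library. For GW5074 this is not an upper bound, since the factor was the lowest of the 4 classes but not of all. Without correction for depth, 348 neutrophil-like cells of the WT DMSO library had at least 1000 UMIs against 5 and 10 in the others. Open are a difference between pools or in the sort, and an effect of the compound or of the lost receptor, which 1 library per group cannot separate.

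Fkbp5, induced by glucocorticoids, was below WT DMSO with GW5074 in all 7 compared classes, though in conventional dendritic cell 1-like cells the ratio of 1.23-fold had an interval that includes 1 (0.971 to 1.56). Free neutrophil RNA is argued against as the whole cause. In 6 of 6 other classes the excess of Fkbp5 was over 2 times what S100a8 allowed (2.45 to 11.9 times). These are point estimates, and in conventional dendritic cell 1-like cells (2.45 times) the excess lay within counting error. The allowance used the ratio of both genes in WT DMSO neutrophil-like cells, so free RNA with another ratio or from other cells was not tested. A general difference in glucocorticoid response between the pools stays open: the median of other targets was under percentile 2.5 of random lists in 1 of 7 classes (resident alveolar macrophage-like, −0.17, percentile 0.71), which by the bound set beforehand would have argued against it, but 8 or 9 members that go both ways within wide random ranges exclude nothing, and the median was below 0 in 6 of the 7. The compound alone was at first taken for all classes at once and divided into macrophage and other classes after the values were seen. In classes other than macrophages Fkbp5 was also lower in the KO library, which had no compound, in 4 of those 5 (T cell-like 2.33-fold, conventional dendritic cell 2-like 3.57-fold, migratory dendritic cell-like 2.24-fold and neutrophil-like 4.14-fold). By the bound chosen this went against the compound alone there. It cannot exclude an effect of the compound in the GW5074 library, since both ratios share the WT DMSO library. In the macrophage classes Fkbp5 was not lower in the KO library, with log2 ratios of 0.33 and 0.13, so an effect of the compound there may hold as a hypothesis, which the pools confound.

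Genes beside Clec7a were higher in the KO library. A difference across the whole segment, such as flanking DNA of another strain (an explanation reworded after its values were seen), stays open: the median absolute log2 ratio within 5 Mb of Clec7a was 0.155 in resident alveolar macrophage-like cells, at percentile 13.6 of random lists, and 0.234 at percentile 96.8 in monocyte-derived macrophage-like cells, but a median cannot exclude a change in a few genes, and 4 ratios of genes outside the neighbour list passed the size rule. A general difference between the libraries is argued against only by the pattern's own values, since the medians of 0.47 and 0.53 of the neighbour list, fixed by position before the data were examined, exceeded every random list. That explanation had first been tested on the 5 Mb window, where 86.4% of random lists reached the observed median and which would have left it standing, before the list replaced it. Also open, and untested, are a local effect of the altered locus on nearby genes such as Clec1a and Clec1b, and an effect of losing the receptor.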

How the results depend on the processing

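Alternatives by doublet score, by called doublets, without neutrophil-like cells, by single cluster and without cluster 10 were chosen after the data were seen, the others before. Against WT DMSO, class shares changed sign in 3 cases: conventional dendritic cell 1-like for GW5074 without neutrophil-like cells in the denominator (0.18 to −0.18), plasmacytoid dendritic cell-like for KO at Leiden resolution 2 (−0.31 to 0.18) and T cell-like for KO without the highest doublet scores (−0.11 to 0.13). For KO over GW5074 the called neutrophil-like ratio reversed under the stricter cell filter (1.84 to −0.12), and ratios near 0 changed sign there for B cell-like (−0.038 to 0.36) and migratory dendritic cell-like cells (−0.028 to 0.025). Named genes kept their sign under both scalings, per-cell weighting, both other resolutions, the stricter cell filter and the doublet settings, wherever a value could be had. List medians inside the random range before and after changed sign in 4 to 13 cases per setting. At resolution 2, 8 genes in neutrophil-like cells had none, and at 50 CPM 17 of 126 list medians had too few members. Keeping doublet calls equals the reported setting, since none was removed. Removing them left 42884 of 42888 cells, which were clustered and named anew into 26 clusters. Shifts without called doublets thus mainly show how the classes depend on the clustering, not on doublets. No paired analysis was possible because each group had 1 library. Except where the construction shows it (other genes, cells or denominators), the cause was not tested. Values below are log2 ratios, each for GW5074 over DMSO and KO over WT where both are given. Depth limits the small classes, where Fkbp5 rested on 8 UMIs in neutrophil-like and 14 in T cell-like cells with GW5074.

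The combined macrophage share moved from 1.29 and 1.33 to 1.13 and 1.13 with at least 500 genes and at most 10% mitochondrial UMIs, to 1.19 and 1.16 without a cell filter, to 2.93 and 2.93 with genes centred within libraries, to 1.15 and 1.12 without the 10% highest doublet scores, to 0.94 and 1.0 with neutrophil-like cells left out of the denominator, and for KO to 1.42 at resolution 2. The neutrophil-like share moved from −5.14 for GW5074 to −4.23 at resolution 0.5, −5.52 at resolution 2, −4.01 under the stricter cell filter and −4.18 without called doublets, and for KO from −3.30 to −3.93 at resolution 2 and −4.13 under the stricter filter. For KO over GW5074 the neutrophil-like share moved from 1.84 to 0.81 at resolution 0.5 and 0.80 without called doublets, and the combined macrophage share from 0.044 to −0.0058 under the stricter filter, −0.038 without a cell filter, −0.0070 under centring and −0.027 without high doublet scores. The migratory dendritic cell-like share moved from −0.67 and −0.70 to −0.89 and −0.86 under the stricter filter, −0.54 and −0.58 without high doublet scores, and −1.02 and −1.03 without neutrophil-like cells. At a minimum of 50 CPM the covariance in resident alveolar macrophage-like cells was 0.0308 against 0.0419.

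With genes centred within libraries, genes in resident alveolar macrophage-like cells reversed for GW5074 (Krt19 −0.78, Cd2 −0.091, Htr2c −1.02, Kcnip4 −0.93, Abca1 −0.067) and for KO (Krt19 −0.053, Htr2c −0.10, Lepr −0.16, Egfem1 −0.18). In monocyte-derived macrophage-like cells Kcnip4 (−0.088, GW5074) and Cxcl2 (−0.064, KO) reversed. Egfem1 was −0.0906 in cluster 0 alone and Oas1a −0.22 in cluster 3 alone, both for KO. Spp1, below 0 for both comparisons in resident alveolar macrophage-like cells without passing the size rule, was 0.49 and 0.27 under centring, and Ccl9 for GW5074 was −0.015 in cluster 3 alone. Arg1 stayed below 0 in resident alveolar macrophage-like cells but ranged from −2.10 to −0.23 for GW5074 and from −2.54 to −0.79 for KO, nearest 0 under centring. Patj for KO was 0.96 under centring. Of 133 called ratios of named genes and list members, 42 fell under 1.5-fold without reversing in at least 1 setting, 27 of them in resident alveolar macrophage-like cells, among them Oas1a, Zbp1, Cxcl2 and Ptger4. Of 46 list medians outside the random range, 17 stayed outside in every setting that gave a value.

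Centring moved the number of lists apart from random lists in resident alveolar macrophage-like cells for GW5074 from 5 to 10, and in monocyte-derived macrophage-like cells from 5 to 16 and, for KO, from 8 to 14. It reversed medians in the first class for efferocytosis (0.14, GW5074) and, for KO, the profibrotic list (0.30), MEK-ERK targets (−0.49) and chemokines (−0.13). In the other class it reversed type I interferon (−1.23) and NRF2 (0.17) for GW5074 and, for KO, the profibrotic list (0.25), inflammatory cytokines (−0.59), type I interferon (−1.08), cholesterol synthesis (0.10), heat shock (−0.079) and chemokines (−0.57).

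Summing all kept cells gave 17 lists apart for GW5074 in place of 5, over cells of all classes. Against the resident alveolar macrophage-like values, medians reversed for GW5074 in the interferon gamma response (−0.42), MHC class II (−0.26), cholesterol synthesis (0.26), glycolysis (0.17), efferocytosis (0.51), NRF2 (0.31) and chemokines (−0.18). For KO they reversed in the profibrotic list (0.40), matrix remodelling (0.16), MEK-ERK targets (−0.59), cholesterol synthesis (0.035), lysosome (0.31), efferocytosis (0.19) and chemokines (−0.28), and for KO over GW5074 in type I interferon (0.053), interferon gamma (0.014), MHC class II (0.26) and chemokines (0.15).

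At a minimum of 50 CPM, 4 lists instead of 8 were apart for KO in resident alveolar macrophage-like cells and 6 instead of 10 for KO over GW5074 in monocyte-derived macrophage-like cells, from fewer members. Reversed there were type I interferon (−0.054, KO) and inflammatory cytokines (−0.23, KO over GW5074) in the first class and chemokines (−0.14, KO over GW5074) in the other. Weighting each cell alike gave 9 lists instead of 5 for GW5074 in monocyte-derived macrophage-like cells. Without called doublets, MHC class II (0.16) and chemokines (0.15) for KO over GW5074 in resident alveolar macrophage-like cells and, in the other class, interferon gamma (0.10, KO) and MEK-ERK targets (0.11, KO over GW5074) reversed. Without high doublet scores, interferon gamma in monocyte-derived macrophage-like cells reversed for KO (0.23) and KO over GW5074 (0.15), the latter also under the stricter cell filter (0.16).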

Other observations

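No hypothesis was tested in this part, and the genes below were chosen after their values were seen. Cluster 11, led by Vcan, Lcn2, Cd177, Arg1, S100a9 and S100a8 and closest to monocytes by markers, was left out of the named classes since 5 of its 10 leading genes are markers of another class. It made up 7.92% of the WT DMSO library, 0.972% with GW5074 and 0.515% in the KO library. Cluster 22, led by Spock2, Rasl12 and Tdgf1, had 82 cells in the WT DMSO library (0.609%) and 0 in the GW5074 and KO libraries (upper bounds 0.0207% and 0.0317%). H2-T23 was lower in the KO library beyond the macrophage and conventional dendritic cell 1-like classes, by 2.62-fold in T cell-like, 2.01-fold in conventional dendritic cell 2-like and 2.66-fold in migratory dendritic cell-like cells, while in neutrophil-like cells its ratio of 1.83-fold had an interval that includes 1 (0.908 to 4.30). Klhl6 was also lower in neutrophil-like cells, 9.72-fold with GW5074 and 7.06-fold in the KO library. Lars2 was higher with GW5074 in conventional dendritic cell 1-like (1.96-fold), conventional dendritic cell 2-like (1.80-fold), migratory dendritic cell-like (2.06-fold) and neutrophil-like cells (2.54-fold), and stood 1.42-fold above WT DMSO in T cell-like cells, short of the rule. Scgb1a1, an airway secretory gene, was at 69.2, 20 and 17.2 CPM in monocyte-derived macrophage-like cells of the WT DMSO, GW5074 and KO libraries. It was 14.2-fold higher in KO migratory dendritic cell-like cells, from 19 cells, and 361-fold higher in KO neutrophil-like cells, where 4 cells held its 684 UMIs.

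Outside the macrophage classes, the profibrotic macrophage list had medians with GW5074 of 0.66 in T cell-like, 0.67 in conventional dendritic cell 1-like, 0.58 in conventional dendritic cell 2-like, 0.85 in migratory dendritic cell-like and 1.26 in neutrophil-like cells, each above the random range. In the KO library they were 0.49, 0.28, 0.37 and 0.84 in the last 4 of these, above the range, and 0.09 in T cell-like cells, inside it. Lyz2, an abundant macrophage transcript, was also higher in these 5 classes, by 2.42-fold, 2.63-fold, 2.34-fold, 2.77-fold and 2.09-fold with GW5074 and by 2.48-fold, 2.51-fold, 2.1-fold, 2.61-fold and 2.52-fold in the KO library. Macrophage-like cells were a larger share of both these libraries than of the WT DMSO library. Whether free RNA of macrophages adds to the profibrotic medians in the other classes was not tested. The type I interferon response was above the range in all 5 of these classes of the KO library (0.36, 0.39, 0.76, 0.33 and 1.58, in the same order), and with GW5074 in conventional dendritic cell 2-like (0.93) and neutrophil-like cells (1.5). Oxidative phosphorylation was below the range in all 5 in the KO library (−0.31, −0.34, −0.30, −0.31 and −0.47). Cholesterol synthesis with GW5074 was above the range in conventional dendritic cell 1-like (0.28), conventional dendritic cell 2-like (0.73) and migratory dendritic cell-like cells (0.62), opposite in sign to resident alveolar macrophage-like cells, a difference that was not tested. MEK-ERK targets were below it in T cell-like cells, at −1.15 with GW5074 and −0.90 in the KO library, and in migratory dendritic cell-like cells with GW5074 (−0.47), but above it in conventional dendritic cell 1-like cells (0.31 and 0.35).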
